A study of Etroplus suratensis with 2 samples.

How the data were processed

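RNA was sequenced from 2 pooled samples of *Etroplus suratensis*, the green chromide or pearlspot, a cichlid fish of brackish waters in southern India and Sri Lanka. Each pool held RNA from 6 organs of 1 sex. Brain, liver, kidney, spleen and muscle were common to both pools, the male pool also held testis, and the female pool also held ovary. Per the labels' protocols, organs were frozen on dry ice, total RNA was extracted with Trizol, and libraries were made with the Illumina TruSeq RNA kit. There was 1 library per sex, and the labels used here do not say how many fish entered a pool or in what proportions the organs were mixed.

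The deposited table has 1 row per assembled contig, named in the style of the Trinity assembler at its gene level, and 96646 rows in all. It gives raw read counts per contig for each library, made by the authors. Per the submitters' processing notes, the tools used included cutadapt 1.8, which trims adapters, Bowtie2 2.2.6, which aligns reads, and DESeq 1.16.0, a package for count comparison. Which step each served, the assembler's version, the counting program and how reads that fit several contigs were treated are not given in the sources used here. The authors also deposited FPKM, that is, counts divided by contig length and by a library total, on the usual FPKM scale. Recomputed from the counts and lengths, the FPKM agreed to within a relative 5.52e-08 when the library totals were 20653893 for the male pool and 25478638 for the female pool. Those totals exceed the column sums of the counts, 19788173 and 24649400, and the reads in between were not analysed here. The table gives the number of each base, the length and the GC percent of each contig, per the file headers. The 4 base numbers summed to the length in every row. Every column of the table was mapped to a pool or to a property of the contig.

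The table pairs no gene name, description or sequence with a contig, and no genome or annotation was used here. The 26 lists of organ, germ cell, hormone and immune genes that were fixed before the data were examined could therefore not be matched, and their planned comparison with 10000 random lists was not made. For a table without names, the rule fixed in advance was to name at most 2 contigs in each direction, namely those with the largest log2 ratio among contigs with a mean scaled count of at least 100. No other contig is named.

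With 1 library per sex there is no estimate of the variation between fish or between pools. No differential test was run and no p-value is given. Every difference below is one between 2 libraries, with no replicate check. Counts were scaled between the libraries by the median of ratios, the method of DESeq, over the 74970 contigs with counts in both libraries. Of these contigs, 52.3% had a mean scaled count under 10, and 4302 had exactly 2 male reads per female read. The resulting size ratio of male to female library was 2, although the male library held 0.803 times the counts of the female one. Log2 ratios of male to female were computed after adding 0.5 to the scaled counts, for the 36872 contigs with a mean scaled count of at least 10, and contigs at least 4-fold apart were counted. Intervals are 95% intervals, exact (Clopper-Pearson) for the ratio of a contig and Wilson for shares of counts. They cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules and no other error could be estimated. A count under 3 was treated as at the floor, which corresponds to 0.152 CPM (counts scaled to the library total) in the male library and 0.122 in the female library.

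The alternatives fixed before the data were examined were scaling by edgeR's TMM and by total counts, a prior count of 5, a filter of at least 1 count in either library and a minimum mean of 100. Further alternatives were chosen after seeing the data: counts summed per Trinity component (the contigs that share an identifier up to its last field), a median of ratios over the 4506 contigs with a mean of at least 1000, a minimum length of 500 bases, and an FPKM threshold of 5 in place of 1. The TMM size ratio computed here, 1.85, equalled that of edgeR 4.0.16. The count of contigs past 4-fold was tested on simulated data for the male and female pools, with all 96646 contigs drawn at the real library sizes. The rates cover only contigs with an expected count of at least 10 at the size of the smaller library, and the changed contigs were chosen among these. All 100% of contigs changed 16-fold and 99.0% of those changed 8-fold were counted, against 0.00808% of unchanged contigs. The simulated counts held counting error alone, with no variation between pools. These rates therefore check the computation and are not error rates for real pools. The simulated data gave a median-of-ratios size ratio of 0.806 against a true one of 0.803, so they did not hold the departure between scalings seen in the real libraries, and these rates do not cover it. In the same simulation 95.9% of the counting intervals held the true ratio, again over contigs with an expected count of at least 10. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.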

Results

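The series set out to profile RNA from organs linked to growth, reproduction and immunity in male and female *Etroplus suratensis*. It comprised 1 pooled library of male organs with testis and 1 pooled library of female organs with ovary. The male library held 19788173 counts and the female library 24649400 counts over 96646 assembled contigs. The contigs belonged to 69911 Trinity components, of which 10582 had more than 1 contig. Contig length ranged from 201 to 31248 bases with a median of 372 and an N50 of 2438, and 22866 contigs reached 1000 bases. The median GC content was 43.0%. The only comparison the design implies is that of the male pool with the female pool, and it has no replicates. It is described here by the groups of contigs that differed, since the contigs carry no gene names.

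The male pool spread its reads over more contigs than the female pool. In the male library 93251 contigs had at least 1 read, against 78352 in the deeper female library, and 74920 would be expected in the female library at the male depth. By the FPKM deposited by the authors, 50905 contigs reached an FPKM of 1 in the male pool and 25995 in the female pool. Of these, 22192 contigs reached it in both pools, 28713 in the male pool alone and 3803 in the female pool alone. The median contig was 372 bases long, so an FPKM of 1 can rest on few reads. At higher levels the pools came closer, with 15243 male and 11902 female contigs at an FPKM of at least 5. At an FPKM of at least 100 there were 556 male and 517 female contigs. By CPM the order reversed at 100, with 1413 male and 1923 female contigs, and at 1000 it was 99 male against 71 female. The numbers of contigs past an FPKM or CPM rest on each library's own total. Comparing them between the pools amounts to scaling by total counts, so they are not free of the choice of scaling. Total counts gave a size ratio of male to female library of 0.803, against 2 by the median of ratios. These numbers were not recomputed under another scaling.

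The most abundant contigs took similar shares of both libraries, and the difference lay in the tail. The 10 most abundant contigs held 6.25% of male counts (95% Wilson interval 6.24 to 6.26) and 7.12% of female counts (7.11 to 7.13). The 1000 most abundant held 48.3% (48.2 to 48.3) in the male pool and 48.1% (48.0 to 48.1) in the female pool. Outside the 10000 most abundant contigs of each library lay 14.2% of male counts (14.1 to 14.2) and 7.64% of female counts (7.63 to 7.65). Outside the 20000 most abundant lay 4.80% of male counts (4.79 to 4.81) and 1.70% of female counts (1.70 to 1.71). These gaps were larger than counting error, and the spread between pools of the same sex is unknown.

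**Figure D1:**
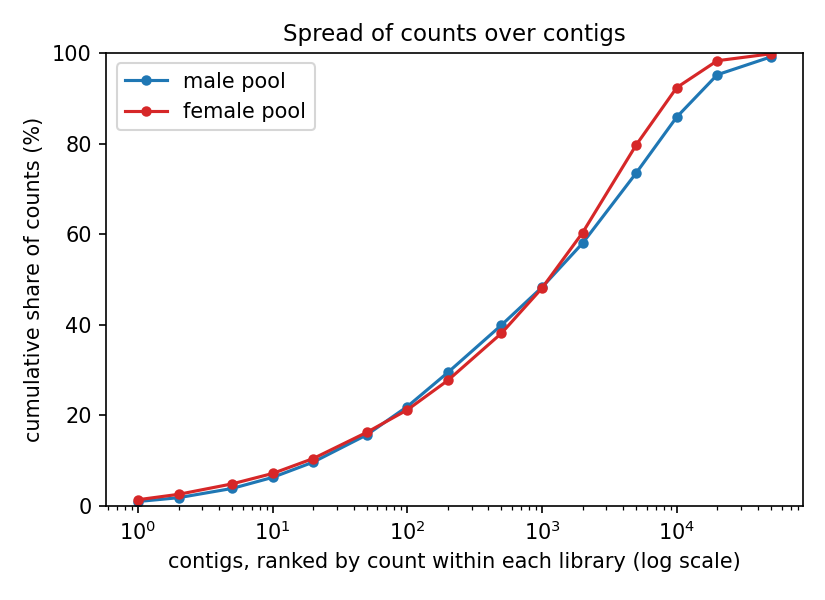
Cumulative share of all counts (%, y axis) against the number of contigs ranked by count within each library (x axis, log scale) for the male pool and the female pool, 1 library each. The curves run close together up to 1000 contigs (48.3% male, 48.1% female) and separate at 10000 contigs, where the male curve is at 85.8% and the female curve at 92.4%.

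A group of contigs was far higher in the female pool and took a large part of its reads. Among the 36872 contigs with a mean scaled count of at least 10, 3079 were at least 4-fold higher in the female pool under all 4 scalings tried. This minimum was set under the median of ratios, and 2690 of the 3079 also met it under each of the other scalings. The 3079 contigs held 36.61% of female counts (95% Wilson interval 36.59 to 36.62) and 1.71% of male counts. Their median length was 1416 bases, and 594 of them had no male read. Of these contigs, 483 were at least 64-fold higher in the female pool under all 4 scalings, and they alone held 19.96% of female counts (19.94 to 19.97) and 0.0357% of male counts.

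The contigs that were higher in the male pool under all 4 scalings had fewer reads, but male-higher and female-higher contigs met unlike cuts. Before the prior count, a scaling moves every log2 ratio by the same amount, so the most extreme scaling set each cut. For male-higher contigs this was the median of ratios, and for female-higher ones the median over contigs with a mean of at least 1000. On the total-count scale the male cut was the stricter one. Total counts alone gave 12030 male-higher and 3329 female-higher contigs. At least 4-fold higher in the male pool under all 4 scalings were 3236 contigs, with 7.24% of male counts (7.23 to 7.25) and 0.368% of female counts. Their median length was 1055 bases, and 532 of them had no female read. The median count in the higher pool was 81 reads for these contigs and 407 reads for the female-higher ones. At least 64-fold higher in the male pool were 402 contigs, with 1.71% of male counts (1.70 to 1.71). Contigs with at least 1000 reads in one pool and under 3 in the other numbered 76 for the female pool, with 5.24% of its counts, and 16 for the male pool, with 0.150% of its counts. At lower depth, 829 contigs had at least 20 male reads and no female read, and 454 had at least 20 female reads and no male read.

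Among contigs with a mean scaled count of at least 100, the 2 with the largest log2 ratios of male to female were TRINITY_DN19225_c3_g1 and TRINITY_DN17879_c0_g1. TRINITY_DN19225_c3_g1, 6683 bases long with 52.8% GC, had 121713 male and 20 female reads, or 882 against 0.117 FPKM. Its log2 ratio of male to female was 11.55, with a counting interval of 10.94 to 12.28, under the median of ratios. It was 12.85 with scaling by total counts and 13.16 with the median of ratios over contigs with a mean of at least 1000, so the scaling moved it by more than counting error. This contig alone held 0.615% of male counts. TRINITY_DN17879_c0_g1, 3906 bases long with 54.1% GC, had 35688 male and 6 female reads, or 442 against 0.0603 FPKM. Its log2 ratio was 11.46, with a counting interval of 10.42 to 12.98, and became 12.73 and 13.03 under the same alternatives.

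The 2 contigs with the largest ratios of female to male, under the same minimum, had no male read. TRINITY_DN16940_c5_g12, 1530 bases long with 45.4% GC, had 106611 female reads and an FPKM of 2735, and held 0.433% of female counts. Against a floor of 3 counts in the male library it was at least 71074-fold higher in the female pool by scaled counts, at least 28529-fold higher with scaling by total counts and at least 22931-fold higher with the median of ratios over contigs with a mean of at least 1000. TRINITY_DN18776_c1_g4, 2294 bases long with 44.99% GC, had 77460 female reads and an FPKM of 1325. The corresponding bounds for TRINITY_DN18776_c1_g4 were 51640-fold, 20728-fold and 16661-fold. The 2-sided exact counting intervals, which are wider than this floor, ended at log2 ratios of male to female of -15.82 for TRINITY_DN16940_c5_g12 and -15.36 for TRINITY_DN18776_c1_g4 under the median of ratios. The proteins that these 4 contigs encode and their places in the genome were not analysed here.

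How many contigs leaned to each sex depended on how the libraries were scaled. With the median of ratios over all contigs, 3236 contigs were at least 4-fold higher in the male pool and 7968 in the female pool, so that 28.9% of the contigs that far apart were male-higher. The TMM scaling gave 3632 and 7485, or 32.7% male-higher. Scaling by total counts gave 12030 and 3329, or 78.3% male-higher, and moved the size ratio so that log2 ratios before the prior count lay 1.32 further towards the male pool. A median of ratios over contigs with a mean of at least 1000 gave 15503 and 2690, or 85.2% male-higher. Which sex had more of the higher contigs therefore changed with the scaling. Counting error alone, with equal levels in both pools, would put 21.1 contigs past 4-fold in the male direction and 1.156 in the female direction under the first scaling. The counting interval lay wholly beyond 4-fold for 1365 of the 3236 male-higher and 6494 of the 7968 female-higher contigs. Some 42.5% of the contigs, 15686 in number, were under 2-fold apart under that scaling.

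**Figure D2:**
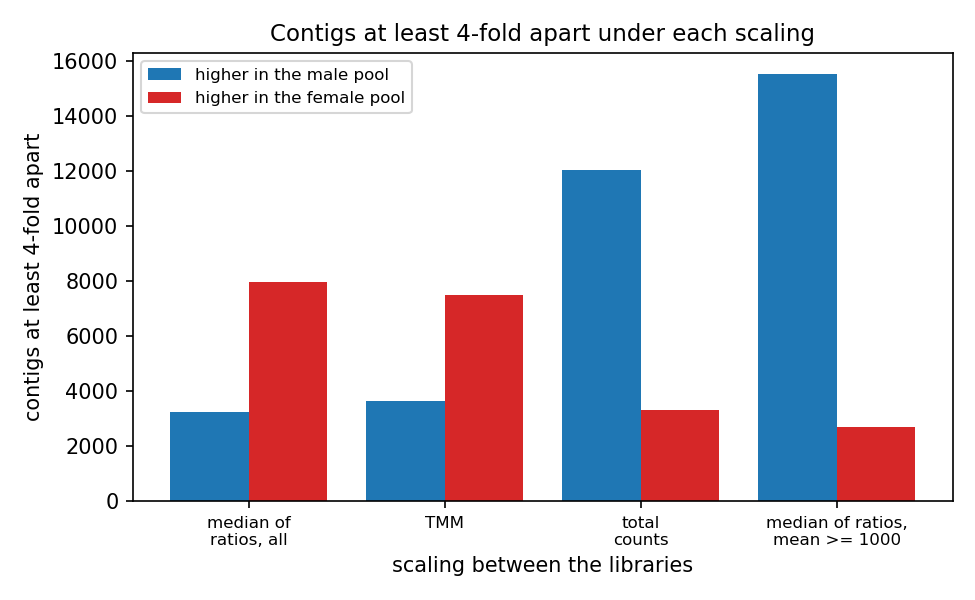
Number of contigs at least 4-fold apart (y axis) under 4 scalings between the libraries (x axis). Bars show contigs higher in the male pool and in the female pool, from 1 library each. Male-higher contigs number 3236 and female-higher ones 7968 with the median of ratios over all contigs, and 12030 and 3329 with total counts.

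The ratio between the pools changed with abundance under each scaling. Under the median of ratios, the median log2 ratio of male to female was 0.26 (quartiles -0.82 and 1.27) for the 18233 contigs with a mean scaled count of 10 to 100. It was -0.65 (quartiles -1.86 and 0.45) for the 13464 contigs with a mean of 100 to 1000, and -2.03 (quartiles -3.20 and -0.84) for the 4905 with a mean of 1000 to 10000. For the 270 contigs with a mean above 10000 it was -1.58, with quartiles from -8.77 to 0.20. Scaling by total counts moved the same medians to 1.55, 0.67, -0.71 and -0.26. The share of contigs at least 4-fold higher in the female pool, by the median of ratios, was 12.5% at a mean of 10 to 100. It was 22.8% at 100 to 1000, 50.8% at 1000 to 10000 and 48.1% above 10000. The male-higher share was 13.5%, 5.36%, 1.06% and 1.85% in the same classes. These shares by class were not recomputed under another scaling.

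**Figure D3:**
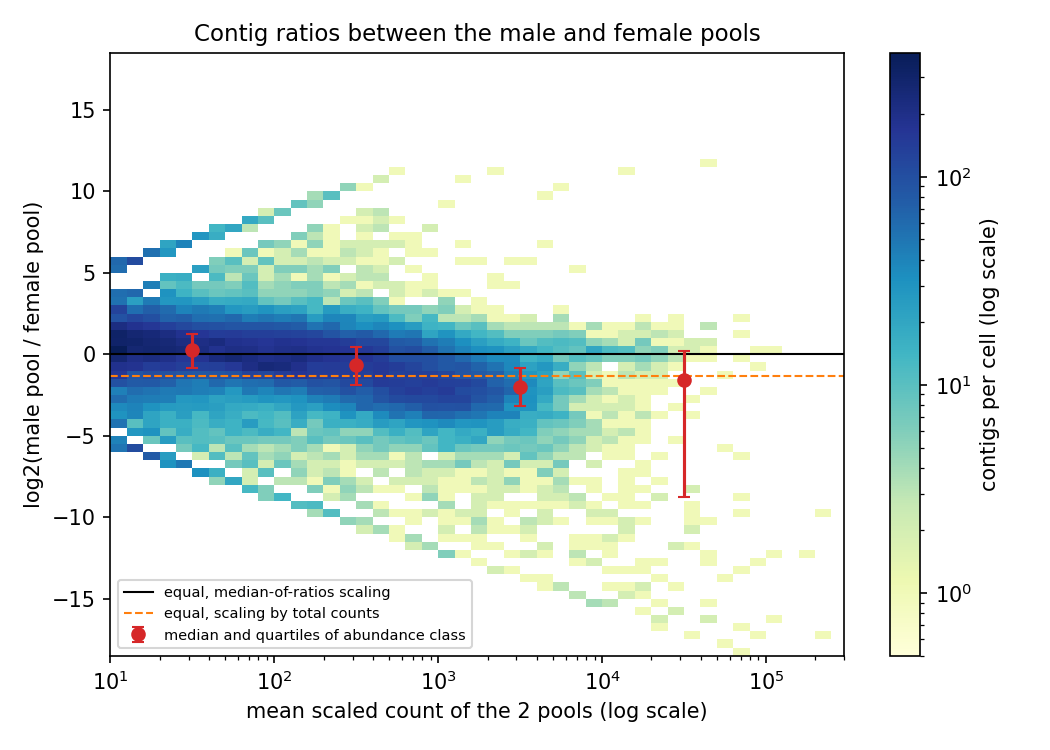
Log2 ratio of male to female pool (y axis) against the mean scaled count of the 2 pools (x axis, log scale), with colour for the number of contigs per cell (log scale). Points and bars are the median and quartiles of 4 abundance classes, which run from 0.26 in the lowest class to -2.03 at a mean of 1000 to 10000, and the lines mark equal levels under the median of ratios and under total counts.

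Female-higher contigs were more frequent at high GC content. Their share of all 36872 contigs was 12.3% under 39.3% GC, 27.6% from 45.7% to 49.1% GC and 26.3% above it, under the median of ratios. At a mean of 100 to 1000 it was 15.2% in the lowest of these GC classes and 29.8% in the highest. At a mean of 10 to 100 it was 10.2% and 15.6%. The male-higher share also rose there, from 9.86% in the lowest GC class to 13.5% in the highest. Over all contigs the male-higher share was 7.65% and 8.54% in these 2 classes. Under the median of ratios, the median GC content was 44.2% in male-higher contigs (quartiles 40.6 and 47.8), 45.7% in female-higher contigs (42.3 and 49.0) and 43.3% in contigs under 2-fold apart (39.4 and 47.4). Across contigs, which are not independent replicates, Spearman's rho between GC content and the log2 ratio was -0.11 over all 36872 contigs. Within abundance classes it was -0.0037 at a mean of 10 to 100, -0.11 at 100 to 1000 and -0.10 at 1000 or more. Among contigs with a mean of at least 1000, the female-higher share was 34.7% in the 190 contigs under 39.3% GC, and 54.6% in the 1090 with at least 49.1% GC.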

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

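The test of an even background of DNA was chosen after the results were seen.

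The library totals behind the deposited FPKM exceed the counts in the table by 865720 reads in the male pool, or 4.19% of its total, and by 829238 reads in the female pool, or 3.25%. These reads were picked out because they are in none of the counts analysed here. Which reads they are is not known.

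Contigs of low abundance lay further towards the male pool than abundant ones: the median log2 ratio at a mean of 10 to 100 exceeded that at a mean of at least 1000 by 2.29, and by at least 1.66 over 4 scalings and 2 kinds of mean. Reads of an organism with a different GC content were looked for in the male-higher contigs of the low class. Their median GC content was 1.25 points above that of contigs under 2-fold apart, with an interquartile range 0.869 times as wide. This argues against such reads confined to the male-higher contigs. The test cannot decide where they also reached the contigs under 2-fold apart. Total counts move log2 ratios by 1.32 towards the male pool, so under that scaling those contigs lay towards it too. Genomic DNA spread evenly in the male library stays open: 116 of 13254 contigs of at least 2000 bases, or 0.875%, had a male FPKM under 0.2, where a strictly even background predicts under 10, and 359 lay under 0.713, or 0.5 times the median male excess of 1.43 FPKM in the low class, but these are a small part of the long contigs, and 288 had a female FPKM under 0.2. Within the low class the median log2 ratio was -0.16 for contigs of 201 to 500 bases and 0.18 at 500 to 1000. It was 0.54 at 1000 to 2000 and 0.74 at 2000 to 4000 bases. Such a background would also give this direction, since it adds reads in proportion to length. The direction was not particular to the low class. Spearman's rho between length and the log2 ratio across contigs was 0.17 in the low class, 0.11 at a mean of 100 to 1000 and 0.12 at 1000 or more. Over all tested contigs it was -0.16. A broader set of transcripts in the testis, which is known for broad transcription in many vertebrates, stays open as a hypothesis, as do an organism of similar GC content and unequal organ shares in the pools, none of which was tested.

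Contigs at least 64-fold higher in the female pool held a large share of its counts, namely 881 contigs with 22.9% under the median of ratios. A GC bias acting at an extreme of GC content would place these contigs there. Their read-weighted mean GC of 46.4% instead lay between the quartiles, 43.1% and 48.5%, of contigs with a mean of at least 1000. That reference is not independent. It holds 312 of the 881 contigs, and 2621 of its 5175 contigs were at least 4-fold higher in the female pool. The test cannot decide on a graded GC bias. In that reference the female-higher share was 34.7% under 39.3% GC and 54.6% at 49.1% or more. Pieces of 1 or 2 assembled components are argued against, since the 2 largest of 799 components held 12.8% of the female counts of the 881 contigs. Transcripts of the ovary, or of female liver, stay open as an untested biological hypothesis, and with 1 library per sex so does a difference between the fish pooled.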

How the results depend on the processing

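The number of contigs at least 4-fold apart, 3236 male-higher and 7968 female-higher, changed by less than 1.5 times with TMM scaling, with a prior count of 5 and with a minimum length of 500 bases. It became 12030 and 3329 with total counts, 22063 and 12473 with no filter except 1 count, and 1761 and 4288 with counts summed per Trinity component, which leaves 21786 units to test. It became 15503 and 2690 with the median of ratios over contigs with a mean of at least 1000. With a minimum mean of 100 the male-higher number was 779 and the female-higher number 5690 of 18639 contigs tested. The male-higher share of tested contigs fell from 8.78% to 4.18% and the female-higher share rose from 21.6% to 30.5%. This minimum removes the 18233 contigs with a mean of 10 to 100, of which 13.5% were male-higher and 12.5% female-higher. The shift is therefore the change with abundance given above. The share of male-higher contigs among those 4-fold apart ran from 12.04% with a minimum mean of 100 to 85.2%, and was 63.9% with no filter. The contigs tested change with the scaling, since the filter acts on scaled counts. The median-of-ratios size ratio rests mostly on contigs with few reads, as 52.3% of its contigs had a mean under 10. The 4 named contigs kept their direction under each alternative run on them. That is no check of them, since they were picked for the largest ratios and the scalings moved log2 ratios by at most 1.63. The 10 most abundant Trinity components held 7.08% of male and 8.82% of female counts. The length filter, the component sums, the median over abundant contigs and the FPKM threshold of 5 were chosen after seeing the data. The alternatives fixed in advance for gene lists and for sums per gene name were not run, since the table names no genes. No paired analysis was possible because each sex had 1 library, and leaving out a replicate was not possible for the same reason. Depth limits the low end: 3 reads correspond to 0.152 CPM in the male pool and 0.122 in the female pool.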

Other observations

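The prediction for the correlation within components was set down before its result was seen. The count of components with both directions was chosen after. The thinning of abundant contigs and the numbers of contigs by CPM had no prediction set down. Ratios between the pools were correlated between contigs of 1 Trinity component, with many exceptions. Across 5697 components with at least 2 contigs at a mean of 10 or more, with 1 random pair of contigs from each, Spearman's rho of the log2 ratios was 0.40, and the highest of 100 shuffles within abundance classes was 0.11. If such contigs are pieces or near copies of 1 transcript, a rho above 0.5 was predicted, and below 0.2 if they are unrelated, so the value of 0.40 leaves this hypothesis open.

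Some components held contigs that went in opposite directions. Of the 5697 components, 430 had 1 contig at least 4-fold higher in the male pool and another at least 4-fold higher in the female pool. At a mean of at least 100, 135 of 3167 components with at least 2 such contigs did. The 100 shuffles within abundance classes gave 224 to 276 such components at that mean. Opposite directions were thus rarer there than in any shuffle. No shuffle is given for the 430 components. With scaling by total counts there were 275 such components, against 436 to 520 in 100 shuffles under that scaling. Abundant contigs thinned to the depth of the low class, with a median of 44 reads over both libraries, moved their median log2 ratio by 0.062. Male contigs also outnumbered female ones at 1000 CPM, 99 against 71, while at 100 CPM female contigs did, 1923 against 1413.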
